A study of Homo sapiens with 12 samples.

How the data were processed

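H3K4me3 was measured by chromatin immunoprecipitation and sequencing in SUM-44 cells transduced with an shRNA against ASH2L or against LacZ. Of 12 samples in all, 6 are H3K4me3 libraries, 3 per group, and 6 are inputs, which were not used here. The labels describe the libraries as biological replicates. The replicate numbers used here follow the order of the records and only name a library. Titles of the LacZ libraries carry different numbers and those of ASH2L libraries 1 and 2 a letter, which library 3 lacks. The labels do not say whether these stand for hairpins or for replicates, although the transduction label is the same for all 3 libraries of each group. The labels list 3 antibody lots without saying which lot went to which library, so lots could not be compared.

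Per the submitters' processing notes, cutadapt, FastQC, Bowtie2, MACS2 and HOMER were used with the hg19 build, and no versions or thresholds are given in the sources used here. Each H3K4me3 library has its own broad peak list, so peaks were called per library and not on pooled samples. In each list the authors deposited the start and end of every peak, a display score, a fold enrichment ratio, and the -log10 of a p-value and of a q-value. The deposited fold enrichment and -log10 values are the caller's own per peak. They were used mainly to describe, rank or filter peaks within a list. Where they are set side by side between lists, their scale may differ from list to list. The lowest deposited -log10 q-value in the lists lay between 1.00 and 1.02. No pair of lists shared a peak with identical start and end, so no list was a copy of another.

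Peaks outside chromosomes 1 to 22 and X were left out, between 53 and 88 per list. No other peaks were removed, so calls in repeats or near centromeres stayed in. Positions are printed counting from 1. The lists contain no read counts, so the depth is unknown and no depth correction was made. A list from a library with less depth or a lower enrichment is shorter for that reason alone, and a region that is not listed fell below the authors' threshold, which does not mean that the mark was absent.

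Peaks of the 6 lists that overlapped by at least 1 bp were merged into regions, and a library called a region if any of its peaks lay in it. Covered length is the number of bases of a region under a library's peaks. A region is called lost here if all 3 LacZ libraries and no ASH2L library called it. Values per library were compared with two-sided exact permutation tests of the difference of means, where 3 against 3 cannot go below 0.1. Overlap between lists was the Jaccard index of covered bases over 15 pairs, tested over the 10 splits of the libraries. Shares of regions have 95% Clopper-Pearson intervals, which cover counting error only. Chromosomes, bins of 10 Mb with at least 20 regions and the 8p11-p12 window were tested with Fisher's exact test, with Benjamini-Hochberg adjustment over chromosomes and over bins. Expected losses came from the lost share within deciles of rank and of covered length, or of rank and distance to the nearest region called in all 6 libraries, with 100000 simulations. Strength is the percentile of fold enrichment within a list, averaged over the LacZ lists.

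Covered length per region was tested with limma (trended and robust) on log2(bp + 500) in regions called in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The log2 differences are on this scale and depend on the 500 bp where a library lists nothing. The regions named were the 5 lost regions with the highest LacZ rank and the 5 narrowed and 5 widened regions with the smallest p, a rule set before the data were examined, as were the tests per library, the 8p11-p12 window and the alternatives except where stated. The tests per chromosome and per bin and those of distance were added later.

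On simulated lists with 200 regions planted as lost and 150 as gained, the merging step counted 200 and 150. In the covered-length test, on 27923 regions with the spread of the LacZ libraries, limma recovered 58% of 100 planted changes of log2 1 and 83% of 100 of log2 2. With the spread within both groups these shares were 14% and 50%. False calls numbered 14 of 155 calls with the LacZ spread and 3 of 67 with the spread within both groups. The simulated spread was drawn per region, without a shift of whole libraries.

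Alternatives were peaks of fold 4 or more, peaks with a q of 0.001 or lower, lists of equal length, peaks within 1 kb joined, a library holding a region only if its peaks cover at least 50% of it, pseudocounts of 100 and 2000 bp, no log, quantile normalization, median centring, regions called in at least 1 library, and leaving out each library. ASH2L library 3 alone was added after the data were seen. Planned comparisons of promoters, gene lists and genomic classes were not run, because the gene table at hand is of a build other than hg19 and positions were not converted. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.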

Results

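The data were 6 lists of H3K4me3 peaks from SUM-44 cells, an established luminal breast cancer line. H3K4me3, trimethylated lysine 4 of histone H3, marks active promoters. ASH2L is a core subunit of the complexes that methylate this lysine, and its gene lies in the 8p11-p12 segment that the series title names as amplified. In 3 libraries ASH2L was knocked down by shRNA, and in 3 control libraries the shRNA was directed at LacZ, which human cells lack. The lists held 18918, 16542 and 30419 peaks on chromosomes 1 to 22 and X for ASH2L libraries 1, 2 and 3, and 31519, 33534 and 34486 for LacZ libraries 1, 2 and 3. The read depth of the libraries is unknown, and the 6 matching input libraries were not analysed here. Regions are given by position in the hg19 build, and no gene names were assigned, because the annotation at hand was of another build. The level of ASH2L itself was not measured in these data, so the knockdown was not checked.

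The first comparison asked whether cells with less ASH2L carried less H3K4me3 across the genome. ASH2L lists held fewer peaks, 21960 ± 7422 (SD, n = 3), than LacZ lists, 33180 ± 1515 (SD, n = 3), and all 3 ASH2L values lay below all 3 LacZ values (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows). The shortfall was uneven. ASH2L libraries 1 and 2 covered 33.2 and 29.1 Mb, while ASH2L library 3 covered 55.3 Mb, inside the LacZ range of 52.1 to 57.4 Mb. The group means of covered length were 39.2 ± 14.1 and 55.2 ± 2.73 Mb (SD, n = 3, exact permutation p = 0.2), and ASH2L library 3 alone lay 0.194 Mb above the LacZ mean.

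Fewer peaks with a fold under 4 made up most of the difference, though a fold of 4 need not mean the same strength in each list. Peaks with a fold enrichment under 4 in the authors' call numbered 4784, 3962 and 13567 in the ASH2L lists and 15017, 16066 and 16934 in the LacZ lists. Peaks at or above 4 numbered 14134, 12580 and 16852 against 16502, 17468 and 17552. The remaining peaks of the ASH2L lists were longer, with a median width of 1497 ± 121 bp against 1174 ± 19.04 bp (SD, n = 3, exact permutation p = 0.1). This direction turned when the weak peaks of every list were left out, to a difference of -176 bp for peaks of fold 4 or more. Broad peaks of at least 4 kb numbered 955, 691 and 2557 in the ASH2L lists and 2008, 2337 and 2401 in the LacZ lists (exact permutation p = 0.4 with n = 3 per group).

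**Figure D1:**
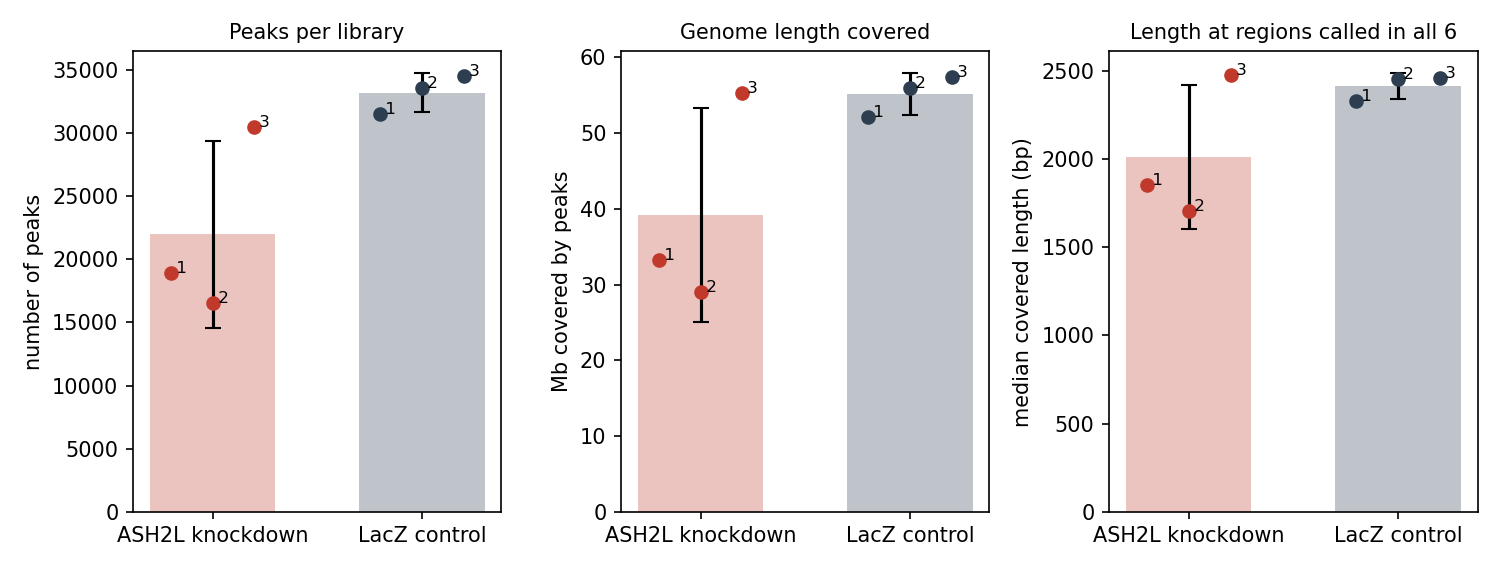
Number of peaks, Mb covered by peaks, and median covered length in bp at the 14834 regions called in all 6 libraries. Points are libraries with their number, bars are group means and error lines are the SD of 3 libraries. ASH2L libraries 1 and 2 lie below the LacZ libraries in every panel, whereas ASH2L library 3, at 55.3 Mb, covers as much as they do.

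The covered bases placed ASH2L library 3 beside the controls. The Jaccard index, the share of covered bases common to a pair of lists, was 0.734 between ASH2L libraries 1 and 2. It was 0.553 and 0.496 between library 3 and these, but 0.694 to 0.702 between library 3 and the LacZ libraries, close to the 0.717 to 0.729 among the LacZ libraries. The mean index within groups was 0.659 and that between groups 0.584, a difference of 0.0749 (one-sided exact permutation over 10 splits, p = 0.2).

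The second comparison asked where the mark was called in control cells and no longer called after knockdown. Merging the 6 lists gave 45451 regions, of which 25397 were called in all 3 LacZ libraries. Of these, 14834 (58.4%, 95% Clopper-Pearson interval 57.8 to 59.0) were also called in all 3 ASH2L libraries, and 1978 (7.79%, 7.46 to 8.12) were called in none of them. No region showed the opposite pattern, and 155 were called in 2 ASH2L libraries and in no LacZ library. A further 6004 regions (23.6%) were missing only from ASH2L libraries 1 and 2. Of the regions in all LacZ lists, ASH2L library 3 lacked 2091 (8.23%), ASH2L library 1 lacked 8595 (33.8%) and ASH2L library 2 lacked 9932 (39.1%). The count of 1978 rose to 8037 without ASH2L library 3 and to 3337 without LacZ library 1, and fell to 262 among peaks of fold 4 or more and to 564 among peaks with a q of 0.001 or lower. Every list was then shortened to its 16542 peaks with the highest -log10 p. This left 88 regions called in all LacZ and no ASH2L libraries and 15 the other way. However, only 6 of the 1978 were still called in all 3 shortened LacZ lists.

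The regions no longer called were the weak and short ones. Weak calls lie nearest the threshold and drop first from a shorter list, so this gradient alone does not point to the knockdown. In the lowest quartile of LacZ fold-enrichment rank, 27.1% of regions (26.0 to 28.2) were called in no ASH2L library and 1.39% in all 3. In the next quartile these shares were 4.10% and 33.0%. In the upper 2 quartiles no region of 6349 each was lost, with an upper Clopper-Pearson bound of 0.0581%, and 99.3% and 100% were called in all 3 ASH2L libraries. By covered length, the lost share went from 24.3% in the shortest quartile through 6.08% and 0.646% to 0.110% in the longest. Lost regions had a median covered length of 629 bp and a median fold of 3.11 in the LacZ lists, against 2420 bp and 11.5 for regions called in all 6 libraries. Regions missing only from ASH2L libraries 1 and 2 were nearly as short and weak, at 841 bp and 3.31.

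**Figure D2:**
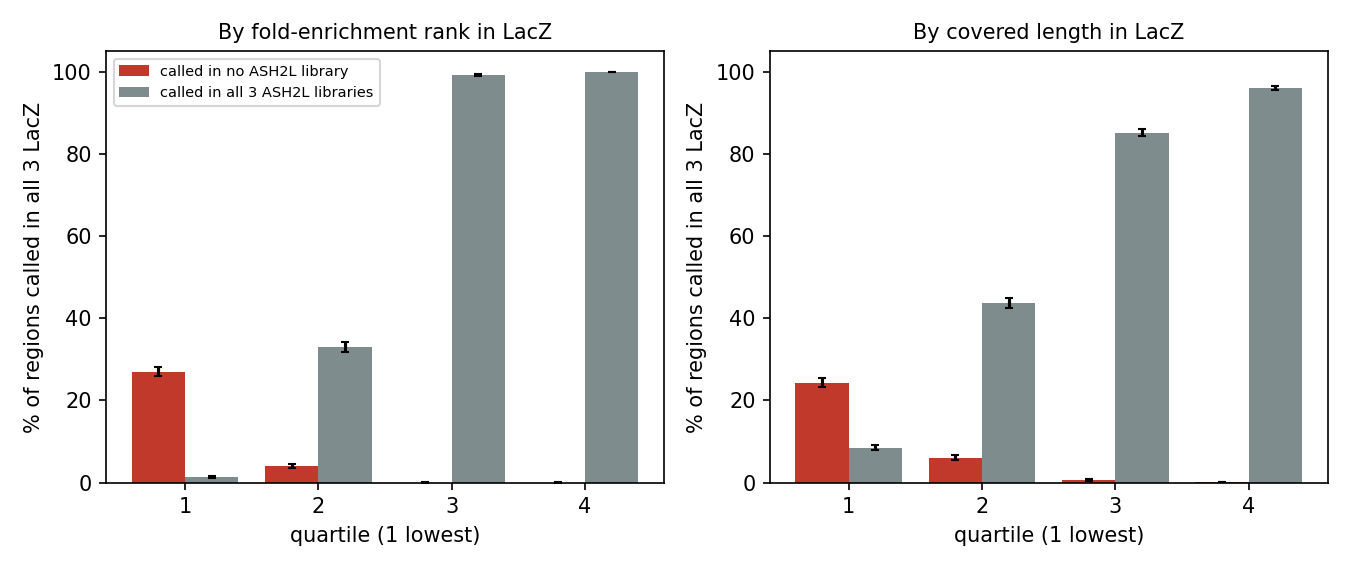
Percent of regions called in all 3 LacZ libraries that were called in no ASH2L library (red) or in all 3 (grey), by quartile of fold-enrichment rank or of covered length in the LacZ lists. Error lines are 95% Clopper-Pearson intervals. The lost share is 27.1% in the lowest quartile of rank and 0 in the upper 2.

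The 5 lost regions with the highest LacZ rank were short peaks that lay far from any region called in all 6 libraries. On chromosome 6, a peak at 32577609 to 32578224 covered 477 ± 130 bp in the LacZ libraries (SD, n = 3) and had a mean percentile of 58.0 in their lists. The others were on chromosome 7 at 90718845 to 90719237, on chromosome 9 at 81436192 to 81436754, on chromosome 3 at 75263632 to 75263881 and on chromosome 14 at 25147938 to 25148356. Their mean covered lengths in the LacZ libraries were 340 ± 64.5, 444 ± 69.9, 232 ± 6.03 and 319 ± 90.6 bp (SD, n = 3). The distances of these 5 from the nearest region called in all 6 libraries were 227, 173, 584, 219 and 234 kb.

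Loss was spread unevenly over the chromosomes. On chromosome 19, 13 of 1318 regions called in all LacZ libraries were lost (0.986%, two-sided Fisher's exact test against all other chromosomes, adjusted p = 9.74e-30 over 23 chromosomes). Chromosomes 17, 22 and 16 also lost few, at 2.36%, 3.04% and 4.24%. Chromosome 5 lost 12.3% (adjusted p = 2.43e-08) and chromosome 6 lost 11.6% (adjusted p = 2.30e-07). In all, 7 chromosomes lost more and 7 fewer than the rest at an adjusted p under 0.05. Set against the losses expected from the rank and covered length of their regions, 4 lost more and 5 fewer, and chromosomes 2, 7 and 8, with 1.01, 1.07 and 1.01 times the expected number, were not among them. Chromosome 19 had 0.286 times, chromosome 22 had 0.463 times, chromosome 5 had 1.32 times and chromosome 6 had 1.32 times the expected number. Regions are treated as independent in these tests, which compare parts of the genome within these 6 libraries, not the conditions.

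**Figure D3:**
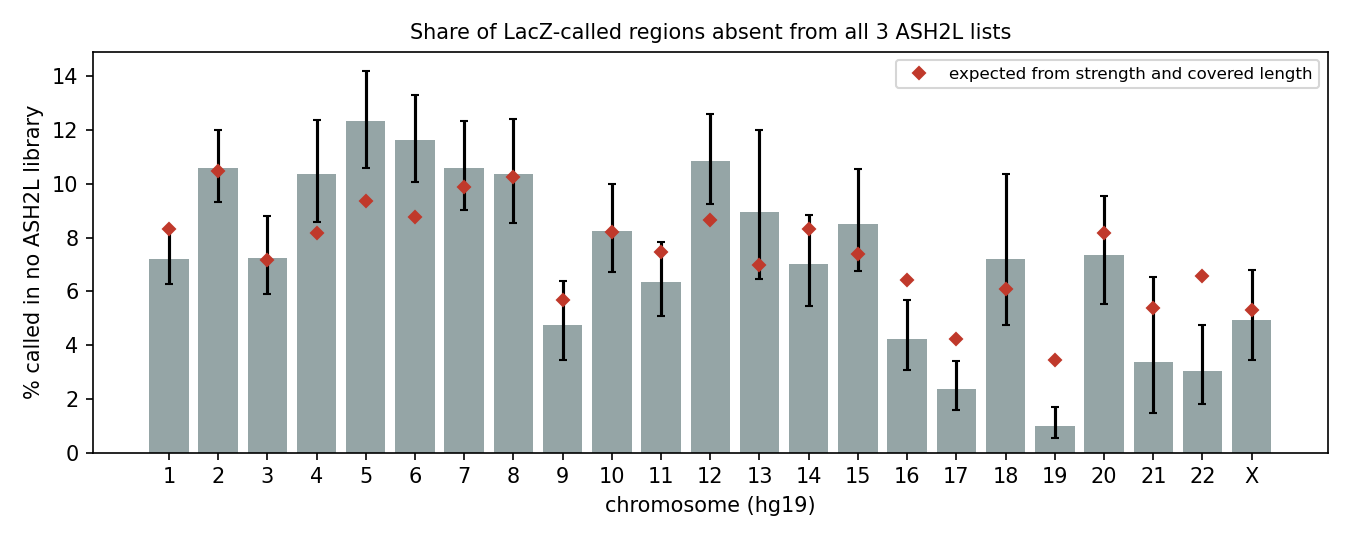
Percent of regions called in all 3 LacZ libraries that were called in no ASH2L library, by chromosome, with 95% Clopper-Pearson intervals. Diamonds mark the percent expected from fold-enrichment rank and covered length. Chromosome 19 is lowest at 0.986% and chromosome 5 highest at 12.3%.

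The third comparison concerned the amplified segment of 8p11-p12, taken as chromosome 8 from 28 to 43 Mb. In this window 18 of 174 regions called in all LacZ libraries were lost (10.3%, 6.25 to 15.9), against 1960 of 25223 elsewhere (7.77%), with an odds ratio of 1.37 (0.839 to 2.24, two-sided Fisher's exact test, p = 0.201). The ASH2L lists held 97, 82 and 191 peaks in the window and the LacZ lists 206, 223 and 213. Regions called in all 6 libraries made up 43.1% of the window's 174 regions called in all LacZ libraries. Without ASH2L library 3 the odds ratio was 1.93 (Fisher's exact test, p = 2.63e-05), among peaks of fold 4 or more it was 0.888, and with lists of equal length it was 4.08 (p = 0.0916). None of these odds ratios is adjusted for the rank and length of the regions. With all 6 libraries, 26.6 losses were expected from the rank and length of the window's regions, more than the 18 found. No such expectation was computed without ASH2L library 3. The low p of that setting therefore cannot be read as loss particular to the window.

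The fourth comparison asked whether the mark was called over a shorter length after knockdown, with the lost regions included. Across 27923 regions called in at least 3 libraries, the mean covered length was lower after ASH2L knockdown in 96.2%, with a median log2 difference of -0.37. It was -0.59 without ASH2L library 3, -0.23 without ASH2L library 2 and 0.0199, the other way, with ASH2L library 3 alone. Every ASH2L library was below every LacZ library at 7063 regions (25.3%) and above every one at 21 (0.0752%). Chance gives 10% for both directions together, but only if no library is shifted as a whole. These shares therefore cannot show a narrowing common to all 3 ASH2L libraries. The 7063 include the 1978 lost regions, which are below by definition. Among the 14834 regions called in all 6 libraries, 2728 (18.4%) were below and 20 (0.135%) above. Taken singly, ASH2L libraries 1 and 2 were below every LacZ library at 85.8% and 94.3% of these, while ASH2L library 3 was below at 20.5% and above at 35.4%. The excess of regions below thus reflects mainly libraries 1 and 2. No region passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.0642, and at an unadjusted p under 0.05 limma called 5912 regions narrower and 2 wider. Without ASH2L library 3 the counts were 16346 narrower and 31 wider. Other settings called up to 1539 narrower regions, the most with a pseudocount of 100 bp, where 1471 of the 1539 were listed in no ASH2L library and 55 were called in all 6 libraries.

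At the regions called in all 6 libraries, the median covered length was 1853, 1704 and 2476 bp in ASH2L libraries 1, 2 and 3 and 2329, 2451 and 2456 bp in the LacZ libraries. The group means of these medians were 2011 ± 410 and 2412 ± 71.9 bp (SD, n = 3, exact permutation p = 0.4).

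The 5 regions with the smallest p for a shorter covered length showed 2 forms. Chromosome 14 at 81994504 to 82001028 and chromosome 5 at 176560370 to 176564784 kept a peak in every ASH2L library but with a shorter flank. The chromosome 14 region was covered over 1221, 1388 and 1999 bp in the ASH2L libraries and over 5397 ± 399 bp (SD, n = 3) in the LacZ libraries, a log2 difference of -1.55 ± 0.16 (SE), where the median over all regions was -0.37. On chromosome 5 the lengths were 1831, 1759 and 2026 bp against 4203 ± 159 bp (SD, n = 3), a log2 difference of -0.99 ± 0.11 (SE). There the peaks of the ASH2L libraries ended at 176562505, 176562561 and 176562716 and those of the LacZ libraries at 176564462, 176564784 and 176564550. The authors' fold enrichment of the chromosome 5 peak was 9.83, 6.83 and 18.4 in the ASH2L libraries and 12.3, 12.9 and 14.8 in the LacZ libraries.

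The other 3 were listed in no ASH2L library. They lay on chromosome 7 at 17344078 to 17348214, on chromosome 8 at 40270764 to 40274187, inside the 8p11-p12 window, and on chromosome 2 at 150845466 to 150848680. Their distances from the nearest region called in all 6 libraries were 2.33, 331 and 400 kb, so the chromosome 7 region lay close to a region that was kept. Their LacZ lengths were 3371 ± 502, 3157 ± 207 and 2721 ± 67.2 bp (SD, n = 3). These were long but weak peaks, with mean percentiles of fold enrichment of 29.3, 3.67 and 28.4 in the LacZ lists. Each of the 5 narrowed regions had the same limma adjusted p of 0.0642, so none passed the threshold. Over the alternative settings the adjusted p ranged from 0.000998 to 0.282 for the chromosome 14 region and from 0.00148 to 0.443 for the chromosome 5 region. For the chromosome 7, 8 and 2 regions it ranged from 0.000926 to 0.240, from 0.000874 to 0.240 and from 0.000922 to 0.282.

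**Figure D4:**
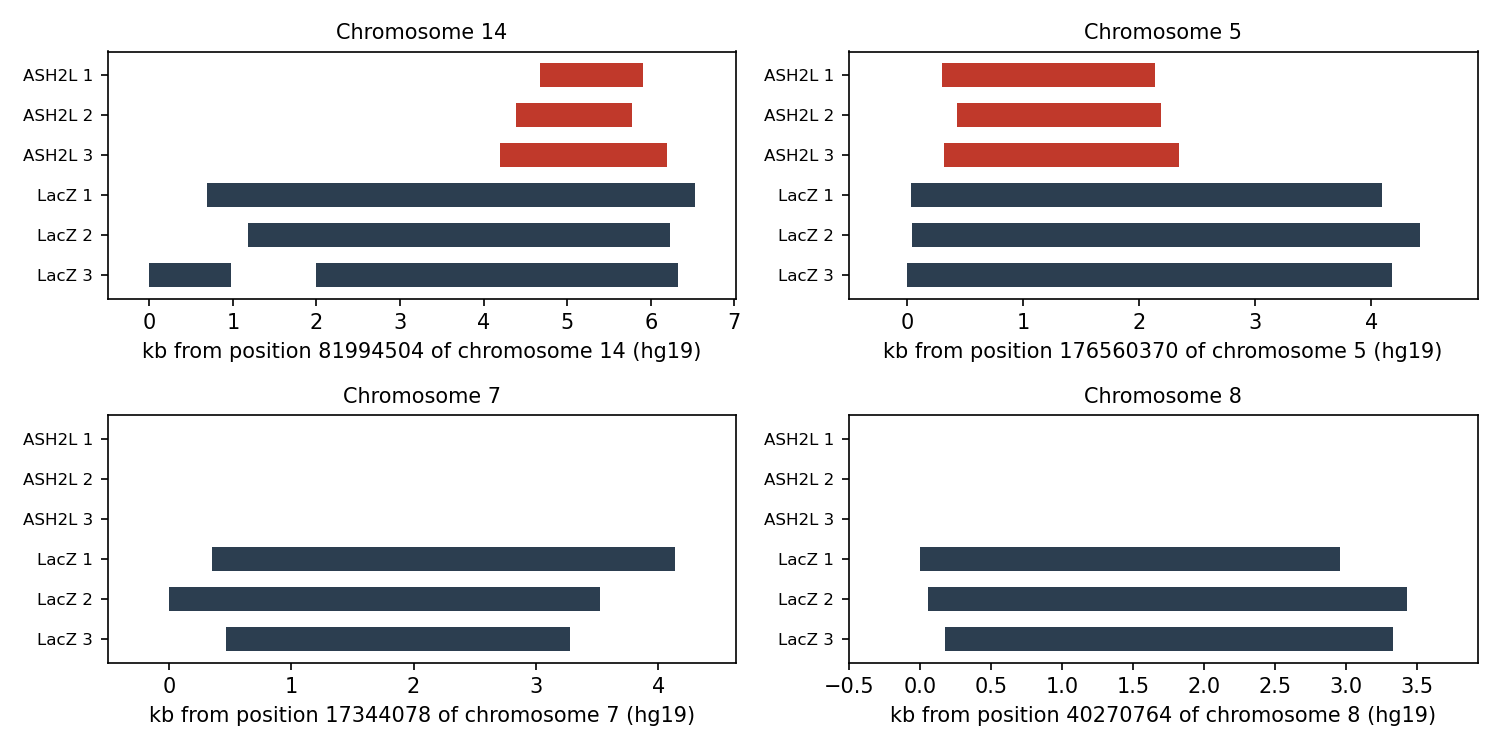
Peaks of each library at 4 of the 5 regions with the smallest p for a shorter covered length, on chromosomes 14, 5, 7 and 8, with ASH2L libraries in red and LacZ libraries in dark blue. The horizontal axis is the distance in kb from the start of the region. On chromosome 5 the ASH2L peaks cover 1831, 1759 and 2026 bp and the LacZ peaks 4203 bp on average, and on chromosomes 7 and 8 no ASH2L library has a peak.

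Of the 5 regions with the smallest p for a longer covered length, none passed the threshold. They were chromosome 7 at 61972434 to 61977018, chromosome 8 at 46848398 to 46856415, chromosome 4 at 49096436 to 49102017, chromosome 8 at 43820930 to 43838843 and chromosome 4 at 153015821 to 153017635. At the first, ASH2L libraries covered 3438, 4585 and 377 bp and the LacZ libraries 248 ± 430 bp (SD, n = 3), with a limma adjusted p of 0.192 that ranged from 0.00601 to 0.591 over the alternatives. The next 3 were covered in ASH2L libraries 1 and 2, were not listed in ASH2L library 3, and had limma adjusted p of 0.233, 0.243 and 0.256. Their adjusted p ranged from 0.00148 to 0.598, from 0.00174 to 0.589 and from 0.00233 to 0.624 over the alternatives, with the lowest in each case without ASH2L library 3. These were very weak peaks, with authors' folds of 1.46, 1.62 and 1.53 in ASH2L library 1 at percentiles of 0.1004, 0.428 and 0.259 of its list. Calls in repeats or near centromeres were not filtered out here, and whether the widened regions lie in such sequence was not checked. The last covered 1155, 1362 and 1713 bp in the ASH2L libraries and 0, 844 and 1002 bp in the LacZ libraries, with a limma adjusted p of 0.269.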

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

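The comparison with ASH2L library 3 alone was chosen after the data were seen, and the other alternatives were set before. Of the alternative values that answer a comparison, 93 kept their direction and side of the threshold or stayed within 1.5 times the reported count, 25 moved further, 5 reversed and 1 newly passed the threshold. Many of the 93 come from the exact tests per library and of overlap, which cannot go below 0.1. Those could not change sides, so only their direction was at stake, and the tally is no measure of robustness. For named regions 136 kept both, 52 newly passed the threshold and 5 reversed. The difference in median width turned to -176 bp with peaks of fold 4 or more, -17.7 bp with a q of 0.001 or lower and -371 bp with lists of equal length, all settings that remove weak, short peaks. Those settings lowered the lost regions to 262, 564 and 88 and raised narrowed regions to 44, 66 and 18. Equal length gave 15 gained regions, and fold 4 or more turned the 8p11-p12 odds ratio to 0.888, while equal length gave 4.08 (Fisher's exact test, p = 0.0916). With ASH2L library 3 alone the covered length was higher by 0.194 Mb, the median log2 difference was 0.0199 and 2688 regions were gained, since a single library then had to call them. Narrowed regions numbered 1539 and 4 with pseudocounts of 100 and 2000 bp, 18 without a log, 37 with quantile normalization, 95 with median centring and 61 with regions called in at least 1 library. Under quantile normalization the lost regions on chromosomes 6, 7, 9, 3 and 14 had log2 differences of 0.00234, 0.179, 0.0355, 0.354 and 0.224, since this scaling gives every library the same distribution. Where not stated, the cause was not tested.

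Leaving out 1 library at a time gave 2023 to 8037 lost regions (8037 without ASH2L library 3, 3337 without LacZ library 1), 0 to 87 gained, 0 to 16346 narrowed and 0 to 31 widened (the highest without ASH2L library 3), and an 8p11-p12 odds ratio of 1.08 to 1.93. No paired analysis was possible because the labels give no replicate numbers shared between the groups. Alternatives for promoters and gene lists were not run, as no annotation of the hg19 build was at hand, and some named regions had no value where too few libraries called them. Depth is unknown, so a region missing from a short list was only below that list's threshold.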

Other observations

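The scalings, the lists of equal length and the covered-length test were planned, and the tests of distance and of dropout for chromosome 19 were set before their result was seen. The tests of depth, fold at shared regions, library 3 alone, strength and length on chromosome 19, splits with equal lists or a pseudocount of 100 bp, distance of lost regions and bins were chosen after it. The other splits were planned, but what they would show was written down after the result was seen. Quantile normalization called 37 narrowed regions and median centring 95, with 34 in both. Of the 34, 3 were called in all 6 libraries, 5 in no ASH2L library and 25 in ASH2L library 3 as the only ASH2L library, so at most of them the whole peak was missing from ASH2L libraries 1 and 2. The following of them were picked after their values were seen. Chromosome 6 at 122940677 to 122946742 was covered over 3866, 5591 and 3625 bp in the LacZ libraries, over 1067 bp in ASH2L library 3 and not at all in the others. Chromosome 9 at 1469613 to 1473556 was covered over 3196, 3829 and 3546 bp in the LacZ libraries and over 510 bp in ASH2L library 3 alone. Without either scaling their limma adjusted p was 0.0642.

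Lost regions were far from regions that all 6 libraries called. Their median distance to the nearest such region was 59.0 kb, against 36.7 kb for regions missing only from ASH2L libraries 1 and 2. Quartiles of LacZ strength were then taken over these sets of regions alone. The difference in median distance, averaged over the quartiles, was 32.0 kb (permutation p = 0.0001, the smallest that 10000 permutations can give). Regions were treated as independent, and the quartiles do not match the sets for chromosome or covered length. Among 291 bins of 10 Mb, 31 lost more and 23 fewer regions than the rest by Fisher's exact test at an adjusted p under 0.05. Against the losses expected from strength and covered length, 3 lost more and 6 fewer at a simulated adjusted p under 0.05. Chromosome 8 from 110 to 120 Mb lost 16 of 47 regions, 2.45 times the expected number (simulated adjusted p = 0.0175). Chromosome 6 from 120 to 130 Mb lost 14 of 60 (2.35 times, 0.0349), and chromosome 22 from 40 to 50 Mb lost 3 of 177 (0.186 times, 0.0116).

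ASH2L libraries 1 and 2 had short lists and ASH2L library 3 did not. The covered length of library 3, 55.3 Mb, was within the LacZ range, so the shortfall in covered length was not seen in all 3 knockdown libraries. With depth unknown, this cannot exclude 1 effect of like size in all 3. More depth or enrichment in library 3 could hide it. At a fold of 4.5 to 5.5, the median -log10 p was 9.62 in ASH2L library 2, within the LacZ range of 9.32 to 9.79. It was 8.12 in library 1, where lower depth may contribute, and 10.15 in library 3, above that range. The window held 2739 peaks in library 2 and 1474 to 1620 in the LacZ lists, so unlike peaks may be compared. It therefore cannot exclude lower depth in library 2. Median fold at regions called in all 6 libraries was 7.98 and 5.89 in libraries 1 and 2, 10.3 to 11.99 in the LacZ libraries and 12.7 in ASH2L library 3. Less H3K4me3 in the cells and a weaker immunoprecipitation predict the same low fold and cannot be told apart without a spike-in, and a knockdown of unequal strength was not tested.

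The real grouping gave 1978 regions called in all of 1 group and none of the other, and the highest of the other splits gave 1134. Only 1 of the 10 splits, the real one, reached that count, but 10 splits are too few for a share under 0.05. With lists of equal length the real grouping gave 88 regions and the highest other split 89, but only 6 of the 1978 remain in all shortened LacZ lists whatever the cause of their loss, so unequal list length may or may not account for them. A further value argues against list length as the whole cause in ASH2L library 3. The 4 long lists were shortened to the 30419 peaks with the highest -log10 p in each. Among them, library 3 alone lacked 1366 regions that the rest called, while no LacZ library lacked more than 951. It also alone called the most regions, 3301 against 2152 to 2363, so it differed more in both directions. For covered length, limma called 0 regions in the real grouping and 3 in the highest other split, and a count of 0 is reached by all 10 splits whatever the data. With a pseudocount of 100 bp the counts were 1539 and 2, and 10 splits are too few for a share under 0.05.

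Chromosome 19 lost few regions. Strong and long regions there do not account for it all, as losses were 0.286 times those expected from strength and covered length. Nor does a short distance to regions called in all 6 libraries, with 0.407 times the expected losses (simulated adjusted p = 0.00138). Regions missing from LacZ library 1 in place of ASH2L library 3 were also rarer on chromosome 19. Their odds ratio was 0.603 (0.436 to 0.834), above the 0.112 (0.0648 to 0.194) of lost regions. These odds ratios are not adjusted for strength or length, and their intervals cover counting error only. With only 1 library swapped for 1 other, they cannot exclude ordinary dropout of weak calls as the whole cause. GC content stays open and was not tested, as no genome sequence was used here. A knockdown effect that differs between chromosomes was not tested either.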
